A study of Mus musculus with 8 samples.

How the data were processed

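RNA was measured by bulk sequencing in 8 libraries of splenic germinal centre B cells from C57BL/6 mice aged 8 to 10 weeks, collected at day 10 after immunization. The cells were isolated with a PNA microbead kit and separated into fractions that the labels name CB and CC, read here as centroblasts and centrocytes, the B cells of the dark and the light zone. The mice carried 2 intact copies of Smarca4 (Smarca4+/+) or 1 (Smarca4+/-). Smarca4, also called Brg1, encodes an ATPase of the SWI/SNF chromatin remodelling complexes. Each of the 4 groups (genotype by cell type) held 2 libraries. The labels do not say whether the replicates were different mice, pools or technical repeats, so every p measured the spread between libraries, which may be technical. They also do not say whether equal replicate numbers in different groups marked 1 mouse.

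The deposited table holds raw read counts per gene, which the authors made from ribosomal RNA depleted total RNA libraries without any normalization. Their processing notes name FastQC, STAR, featureCounts and Subread, R 4.2.1 and the mouse genome build mm10. The versions of the aligner and the counting tools, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited table also holds the other unit, a length column in bases, which was used only in a test of length bias. Of its 55421 gene identifiers, 54587 matched the GENCODE M21 annotation with their version and 55154 had a symbol. Genes that share sequence (histones, immunoglobulin segments, globins, Bcl2a1 copies, mitochondrial genes with nuclear copies, predicted genes) may have gained or lost reads to their relatives. Antisense and overlapping genes are uncertain for want of the strand setting.

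Total counts were 18357578 to 24341805 in the 4 CB libraries and 526353 to 837558 in the 4 CC libraries, with a ratio of the means of 32.7. A count of 0 was read as a level of up to 3 counts, which over both libraries of a group was 0.0730 CPM (the count scaled to a common library total) in Smarca4+/+ CB, 0.0754 in Smarca4+/- CB, 2.56 in Smarca4+/+ CC and 1.88 in Smarca4+/- CC. Such floors cover counting error only, since reads were not marked by molecule. A fold against a group at 0 is given as "at least N-fold", computed against that floor.

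Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 12997, and libraries were scaled by TMM. A quasi-likelihood model with a mean per group was fitted to all 8 libraries (4 residual degrees of freedom), and 5 contrasts were tested 2-sided with Benjamini-Hochberg adjustment at 0.05: genotype in CB, genotype in CC, CC against CB in each genotype, and the genotype by cell type interaction. Standard errors (SE) were derived from the fold change and its F statistic. CPM values use the TMM scaling and are given with their SD (n = 2). Fixed gene lists with at least 3 measured members (34) were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and with fry (limma 3.58.1) beside it. camera compares a list with all other genes, while fry asks whether a list's genes move, on balance, in 1 direction. The lists, the design, the threshold and the alternative settings named first below were fixed before the data were examined. Named genes were also fixed by rule: per contrast the 12 largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between groups (without immunoglobulin segments, predicted genes and clones), up to 4 called members of each list, a fixed set of 12 genes, and the 10 smallest p where fewer than 5 genes passed.

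The fit was checked on simulated counts with the depth and spread of these libraries. Of 100 genes changed 4-fold it recovered 52% for genotype in CB, 42% for genotype in CC, 48% and 32% for CC against CB in Smarca4+/+ and Smarca4+/-, and 9% for the interaction. At 2-fold it recovered 1%, 5%, 2%, 4% and 0% in the same order. False calls numbered 0, 26, 1, 2 and 0 in that order, so that the genotype contrast in CC called more false genes than the others. camera called a simulated list of 30 genes changed 1.5-fold (adjusted p = 2.26e-05) and 0 of 34 random lists. The simulated genes were drawn independently of each other, so this check could not show how often camera calls correlated lists falsely. In the data the estimated correlation was higher in some lists, such as 0.51 for G2/M genes in the genotype contrast in CC.

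The other settings fixed in advance were DESeq2 1.42.0, limma-voom, RLE and total count scaling, no low count filter, a stricter one (at least 50 counts in 2 libraries), no immunoglobulin genes, a replicate block (also within genotype), only the groups compared, and each library left out in turn. Added after the data were seen were the CB libraries thinned at random to 657641 counts, the mean CC total, and a fit without the ribosomal RNA locus and mitochondrial genome genes. With 2 libraries per group no permutation of the labels can reach the threshold, and none was run. Figures were drawn with matplotlib 3.10.9.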

Results

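Gene expression was measured in 8 RNA sequencing libraries of mouse splenic germinal centre B cells, 2 from each combination of Smarca4 genotype (+/+ or +/-) and cell fraction (CB or CC). The comparisons ask how loss of 1 Smarca4 copy alters centroblasts and centrocytes, and how the fractions differ within each genotype. The CB libraries held 18357578 to 24341805 counts and the CC libraries 526353 to 837558. Replicates correlated across genes (Pearson, log2 CPM) at 0.969 in Smarca4+/+ CB and 0.981 in Smarca4+/- CB, against 0.752 and 0.769 in the same genotypes of CC. Genes of the ribosomal RNA locus took 17.4% to 31.1% of each library. Mitochondrial genome genes took 0.699% to 1.40% of the CB counts and 2.24% to 5.86% of the CC counts.

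Smarca4 itself (ENSMUSG00000032187.16, mm10 chromosome 9, 21616169 to 21704230) stood at 950 ± 74.0 CPM in Smarca4+/+ CB and 718 ± 22.6 in Smarca4+/- CB (SD, n = 2), a ratio of 0.756. In the CC libraries it stood at 319 ± 4.35 and 277 ± 46.9 CPM, a ratio of 0.871. The genotype difference was in the direction of the labels in both fractions and did not pass the test in either, with a log2 fold change of -0.40 (SE 0.17, adjusted p = 1) in CB and -0.20 (SE 0.18, adjusted p = 0.607) in CC. The unadjusted p of the edgeR test in CB was 0.0359. Both Smarca4+/- CB libraries (734 and 702 CPM) lay below both Smarca4+/+ CB libraries (897 and 1002 CPM), while the CC libraries (322 and 316 against 244 and 311 CPM) rested on 180 to 262 counts each. In CC the log2 fold change was -0.04 without Smarca4+/- replicate 1 and -0.40 without replicate 2.

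**Figure D1:**
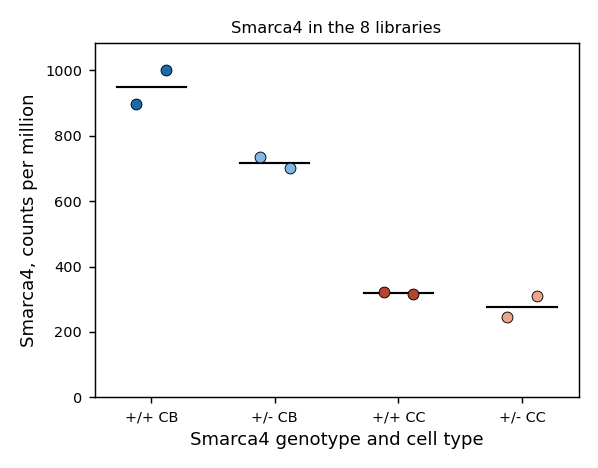
Smarca4 level in CPM in each of the 8 libraries (points) with the group mean (line), by Smarca4 genotype and cell type. The 2 Smarca4+/- CB libraries sit at 734 and 702, below the Smarca4+/+ CB libraries at 897 and 1002, and the 4 CC libraries sit between 244 and 322.

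In Smarca4+/+ cells, mitotic genes were lower and light zone genes higher in CC than in CB. Of 29 measured genes of G2/M and mitosis, 24 fell, 0 rose and 5 did not pass (28 fell when adjusted over the list alone). They included Mki67, the proliferation antigen (log2 fold change -1.87, SE 0.19, from 3936 ± 235 to 1078 ± 72.6 CPM, SD, n = 2), and the mitotic kinases Aurka (-4.04, SE 0.53) and Bub1 (-3.58, SE 0.49). The list's camera adjusted p was 1.66e-31, and adjusted p = 0.103 with an estimated correlation. Replication-dependent histones, made in S phase, fell in 32 of 58 with 26 not past the test (44 when adjusted over the list alone), among them Hist1h1e (-2.14, SE 0.22). That list had a camera adjusted p of 6.31e-27, and adjusted p = 0.116 with an estimated correlation.

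Dark zone genes outside the cell cycle fell in 8 of 10, and in 10 of 10 when adjusted over the list alone. The list's camera adjusted p was 9.58e-10, and adjusted p = 0.0833 with an estimated correlation. Cxcr4, the chemokine receptor that holds B cells in the dark zone, fell from 202 and 192 to 32.2 and 45.8 CPM (n = 2; log2 fold change -2.33, SE 0.30, adjusted p = 0.00187). The transcription factor gene Foxo1 (-0.96, SE 0.19, adjusted p = 0.0149) fell too. Of 26 light zone and activation genes, 8 rose, 0 fell and 18 did not pass (10 rose when adjusted over the list alone). The list's camera adjusted p was 8.2e-08, and adjusted p = 0.0833 with an estimated correlation. Ccnd2, a cyclin of cell cycle entry, rose from 9.93 ± 0.679 to 200.3 ± 91.2 CPM (SD, n = 2; log2 fold change 4.34, SE 0.46), and Myc rose from 26.4 ± 3.65 to 141 ± 17.7 CPM (2.42, SE 0.29). Irf4 (1.77, SE 0.33), Egr3 (1.80, SE 0.34) and the costimulatory ligand Cd86 (1.00, SE 0.24) also rose, while Cd83 stood at 0.61 (SE 0.26, adjusted p = 0.186) and Prdm1 at 2.21 (SE 0.71, adjusted p = 0.0896). Myc, Ccnd2, Irf4 and Cd86 can also be expressed by T cells or macrophages, whose markers were higher in the same libraries, and their share was not separated.

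More genes of memory and naive B cells rose than fell in CC. The summed level of the memory list went the other way, from 2076 and 2116 CPM in CB to 1571 and 1669 CPM in CC. Of 19 memory B cell genes, 11 rose, 3 fell and 5 did not pass (the same counts when adjusted over the list alone), with Cd38 (2.65, SE 0.32), S1pr1 (4.14, SE 0.48) and the survival gene Bcl2 (5.36, SE 0.82) among those that rose. The camera adjusted p of that list was 2.31e-08, and adjusted p = 0.0833 with an estimated correlation. Naive follicular markers rose in 6 of 11 with 5 not past (adjusted over the list alone, 8 rose and 2 fell), among them the complement receptor Cr2 (1.66, SE 0.25). Their camera adjusted p was 1e-06, and adjusted p = 0.0861 with an estimated correlation. S1pr1 and Bcl2 are also expressed in T cells, whose markers were higher in the same libraries. Of 18 genes of migration and confinement, 8 rose, 2 fell and 8 did not pass, with Gna13 (-0.87, SE 0.18) beside Cxcr4 among those that fell. Their camera adjusted p was 0.000107, and adjusted p = 0.0833 with an estimated correlation.

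Among other B cell programmes, 5 of 28 genes of G1/S and DNA replication fell (16 when adjusted over the list alone), with Rrm2 (-1.59, SE 0.27) and Mcm5 (-0.83, SE 0.20). Genes of somatic hypermutation and DNA repair fell in 6 of 20 (8 when adjusted over the list alone), and those of the SWI/SNF complexes in 3 of 24 (6 when adjusted over the list alone). The last were Smarca4 (-1.58, SE 0.18, adjusted p = 0.00119), Bicra (-1.70, SE 0.29) and Bcl7a (-1.29, SE 0.27). The camera adjusted p of these lists was 1.84e-06, 0.000124 and 0.00149, and adjusted p = 0.128, 0.123 and 0.332 with an estimated correlation. Of 20 germinal centre transcription factors 6 fell, such as Bach2 (-1.74, SE 0.28) and Pou2af1 (-1.02, SE 0.21), and 2 rose, Irf4 and Klf2 (camera adjusted p = 0.00544; adjusted p = 0.509 with an estimated correlation). Bcl6 stood at -0.63 (SE 0.22, adjusted p = 0.104). The MYC target list rose in 3 of 30 members, such as Mybbp1a (0.74, SE 0.19; camera adjusted p = 0.000211; adjusted p = 0.336 with an estimated correlation). In the unfolded protein response list 4 of 16 genes rose, such as Pdia4 (2.58, SE 0.32), while 8 were positive and 8 negative. The list's median was 0.12 and its mean -0.45, and camera gave a higher list (adjusted p = 0.00907, or adjusted p = 0.393 with an estimated correlation).

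**Figure D2:**
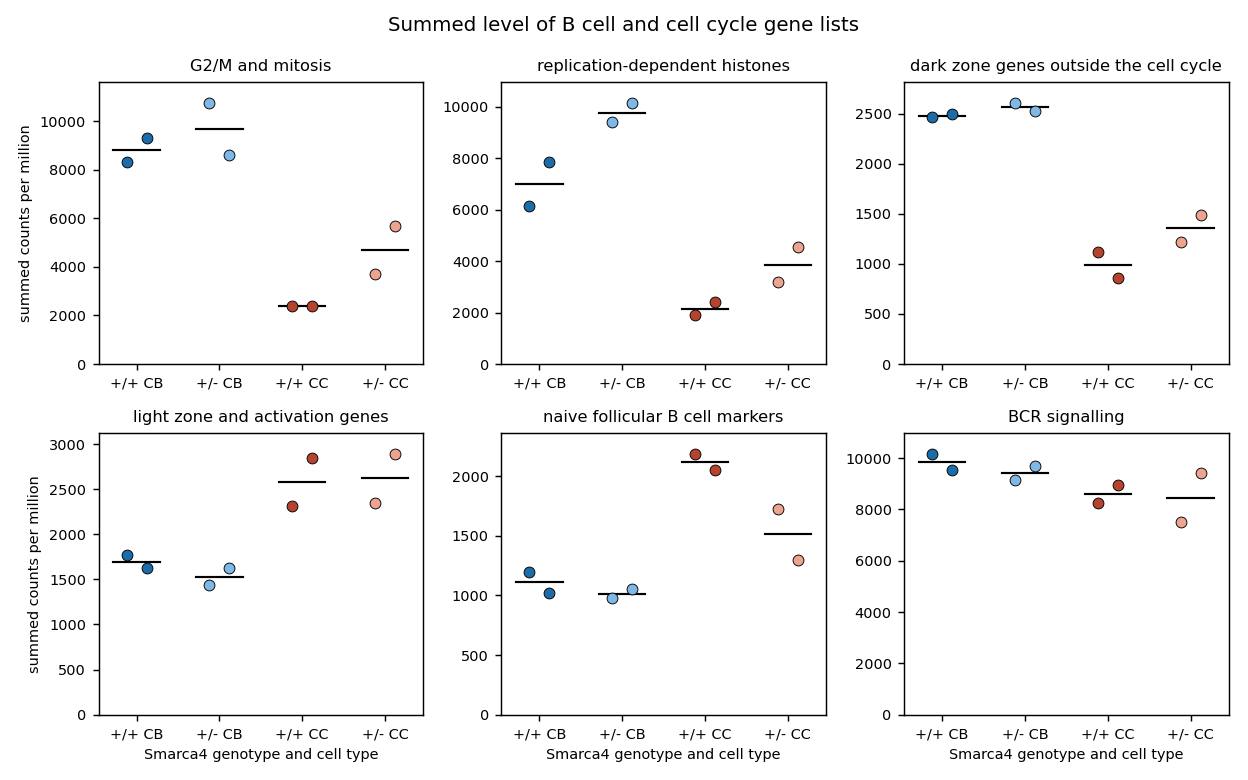
Summed level of 6 gene lists in CPM in each library (points) with the group mean (line), by Smarca4 genotype and cell type. The G2/M genes sum to 2382 and 2388 in the Smarca4+/+ CC libraries and to 3723 and 5692 in the Smarca4+/- CC libraries, below all 4 CB libraries, whose lowest is 8316.

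Markers of other cell types were higher in the same Smarca4+/+ CC libraries. Macrophage and monocyte markers summed to 3744 and 3943 CPM in the CC libraries and to 68.2 and 329 CPM in the CB libraries, and 13 of 17 rose (17 when adjusted over the list alone). They included the complement gene C1qa (4.74, SE 0.55) and the heme oxygenase gene Hmox1 (4.45, SE 0.47). T cell markers rose in 11 of 16 (15 when adjusted over the list alone), with Cd3e at least 1015-fold higher than in CB, where it was at 0. Erythroid markers rose in 7 of 10 (10 when adjusted over the list alone), such as the globin gene Hba-a1 (7.44, SE 0.60). The camera adjusted p was 2.61e-25 for macrophages, 9.43e-19 for T cells and 9.41e-17 for erythroid cells, and adjusted p = 0.0861, 0.0833 and 0.0833 with an estimated correlation. Mitochondrial genome genes rose in 6 of 10, such as mt-Nd2 (1.51, SE 0.18; camera adjusted p = 3.29e-08; adjusted p = 0.236 with an estimated correlation).

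Over all 12997 genes tested in Smarca4+/+ cells, 484 rose and 489 fell from CB to CC. Among the largest increases by rule were those in Cd3e, Ubash3a, Itga5, Il7r, Abcb1a, Car1, Fn1, Svep1, F13a1, Frmd4a and Themis, several of them genes of T cells or myeloid cells. The largest decreases by fitted change were in Hist1h4m, Cenpl, Arhgap33, Hist1h2ah, Cenpi, Dxo, Neurl1b, Bcl2l12, Timmdc1, Cdkn3, Ssna1 and Rgcc. All of them were at 0 in the CC libraries and at least 7.99-fold to 11.1-fold lower. Their rank rests on fitted values over a group at 0, so other genes, such as Aurka, may have fallen as far or further. The median log2 fold change of all genes was -0.19 with TMM, -0.07 with RLE and -0.00404 with total count scaling, and the split of higher and lower genes became 541 and 367 with RLE and 568 and 289 with total counts. Of 34 lists camera called 21, and fry called 14. The camera calls of transcription factors (0.157) and the unfolded protein response (0.073) ended without Smarca4+/+ CC replicate 1, and that of NF-kB genes (0.236) without replicate 2. The count of genes was 222 without Smarca4+/+ CB replicate 1, 226 without Smarca4+/+ CB replicate 2, 292 with only the groups compared, 579 with CB thinned to the CC depth, 1651 without the low count filter and 2167 with DESeq2.

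In Smarca4+/- cells many of the same lists differed between CC and CB, with exceptions. By camera at the preset correlation, ribosomal proteins were higher in Smarca4+/+ CC (adjusted p = 0.00338) and lower in Smarca4+/- CC (adjusted p = 0.000251). Oxidative phosphorylation genes and immunoglobulin V segments were called in Smarca4+/- cells only. How alike the genotypes were over the lists was not tested. Genes of G2/M and mitosis fell in 10 of 29 (26 when adjusted over the list alone), such as Cenpf (-1.78, SE 0.27) and Kif11 (-1.27, SE 0.24), and histones fell in 29 of 58 (47 when adjusted over the list alone), such as Hist1h4c (-2.11, SE 0.32). Their camera adjusted p was 6.86e-19 and 1.47e-30, and adjusted p = 0.122 and 0.0968 with an estimated correlation. Dark zone genes fell in 5 of 10 (7 when adjusted over the list alone), such as Cxcr4 (-1.96, SE 0.27, adjusted p = 0.00435) and the polymerase gene Polh (-2.24, SE 0.37). Light zone genes rose in 9 of 26 (16 when adjusted over the list alone), such as Ccnd2 (3.96, SE 0.46), Myc (2.02, SE 0.28), Cd83 (1.25, SE 0.26) and Cd86 (1.22, SE 0.24). These dark and light zone lists had a camera adjusted p of 6.83e-09 and 1.08e-14, and both had adjusted p = 0.0769 with an estimated correlation. NF-kB genes rose in 3 of 24 (9 when adjusted over the list alone), with Nfkb2 (1.24, SE 0.24) and the feedback inhibitor gene Tnfaip3 (1.51, SE 0.32; camera adjusted p = 2.11e-05; adjusted p = 0.151 with an estimated correlation). In Smarca4+/+ cells 0 of the 24 passed the edgeR test, and that list's camera adjusted p was 0.00576, or adjusted p = 0.336 with an estimated correlation. The genotypes were not shown to differ here, since the interaction had an adjusted p of 0.51 for the NF-kB list and 0.592 for Cd83.

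Memory B cell genes rose in 7 of 19 and fell in 2 in Smarca4+/- cells, with the chemokine receptor gene Ccr6 (6.97, SE 1.15) among those that rose. Their summed level was again lower in CC (1128 and 1297 CPM) than in CB (1917 and 1857 CPM). Naive follicular markers rose in 4 of 11 and fell in 1, with Cr2 (1.60, SE 0.25). Adjusted over the list alone, these counts were 10 and 2 for memory and 6 and 1 for naive genes. The camera adjusted p was 1.31e-06 for memory and 2.87e-05 for naive genes, and adjusted p = 0.0968 and 0.122 with an estimated correlation. Genes of G1/S fell in 4 of 28, such as the replication licensing gene Cdt1 (-1.83, SE 0.31; camera adjusted p = 1.74e-06; adjusted p = 0.122 with an estimated correlation). Among transcription factors 4 of 20 fell, such as Pou2af1 (-1.36, SE 0.21) and Bach2 (-1.34, SE 0.27), and Klf2 rose (3.06, SE 0.66; camera adjusted p = 0.0262; adjusted p = 0.539 with an estimated correlation). The immunoglobulin genes Igkc (-0.92, SE 0.15) and Ighm (-0.86, SE 0.18) and the J chain gene Jchain (-0.93, SE 0.22) fell, 3 of the 13 members of their list, of which 6 were positive and 7 negative (camera adjusted p = 0.131). SWI/SNF subunit genes fell in 2 of 24, Smarca4 and Bcl7a (-1.19, SE 0.27), and genes of hypermutation and repair in 1 of 20 (camera adjusted p = 0.000251 and 0.00343; adjusted p = 0.188 and 0.158 with an estimated correlation). Immunoglobulin V segments had a negative log2 fold change in 137 of 170, of which 1 fell (camera adjusted p = 0.000211; adjusted p = 0.139 with an estimated correlation), and interferon genes a positive one in 20 of 23, with none past the edgeR test (0.000203; adjusted p = 0.157 with an estimated correlation). MYC targets (0.005), migration genes (0.0445) and stromal markers (0.00918) were higher as lists, with adjusted p = 0.411, 0.158 and 0.362 with an estimated correlation. Without CC replicate 1 the calls of transcription factors (0.285), migration genes (0.113) and stromal markers (0.681) ended, and without CC replicate 2 that of MYC targets (0.298). The migration call also ended without CB replicate 1 (0.0528) or 2 (0.0847) and with CB thinned (0.368), and the transcription factor call with RLE scaling (0.0574).

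**Figure D3:**
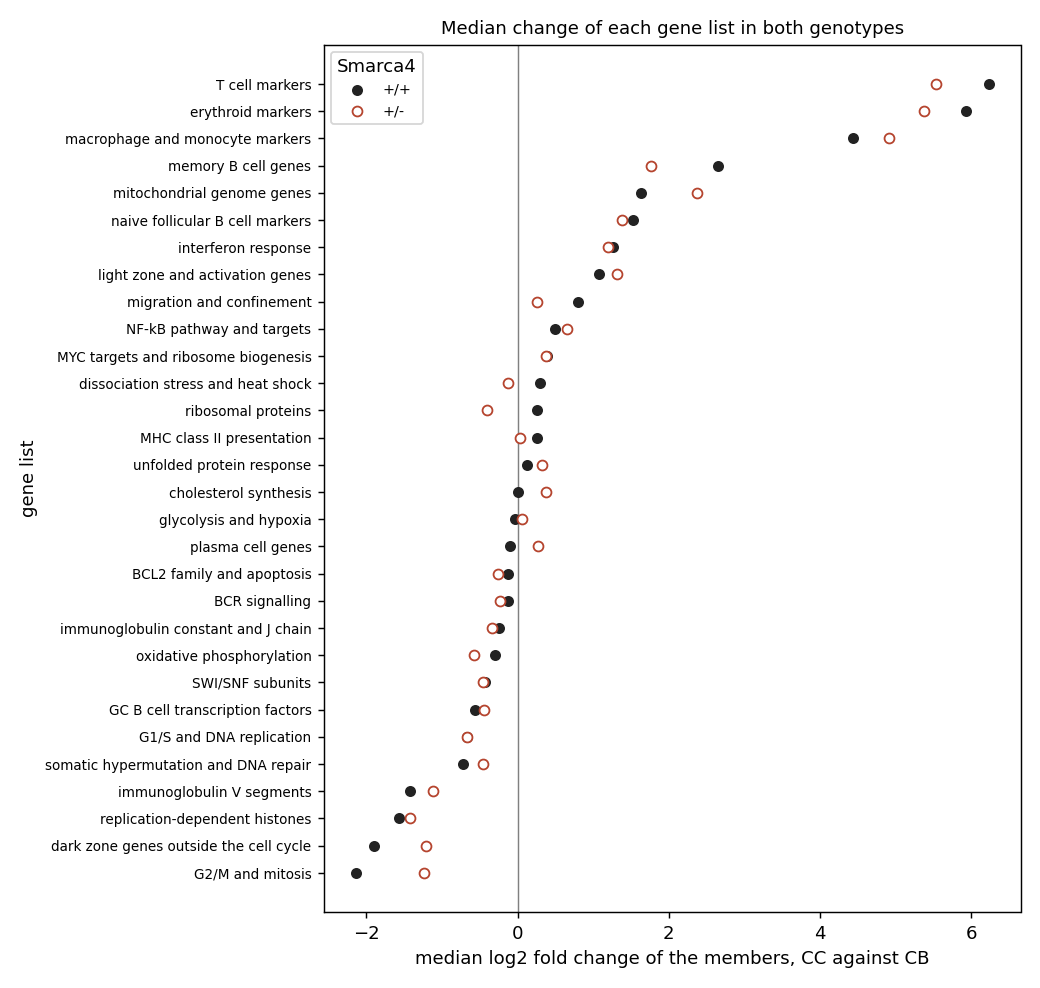
Median log2 fold change of CC against CB for each list with at least 10 measured members, in Smarca4+/+ (filled) and Smarca4+/- (open) cells. The G2/M median was -2.14 in Smarca4+/+ and -1.23 in Smarca4+/- cells, and the ribosomal protein median was 0.26 and -0.40.

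Other-cell markers were again higher in the Smarca4+/- CC libraries. Macrophage markers rose in 13 of 17 (16 when adjusted over the list alone), such as C1qa (5.10, SE 0.57), T cell markers in 10 of 16 (15 when adjusted over the list alone), such as Cd3e (5.75, SE 0.94), and erythroid markers in 6 of 10 (9 when adjusted over the list alone), such as Hbb-bs (5.33, SE 0.59). The camera adjusted p was 2.37e-27, 6.8e-16 and 4.35e-15 in that order, and each had adjusted p = 0.0968 with an estimated correlation. The 2 libraries differed from each other, with macrophage markers summing to 4631 CPM in replicate 1 and 2063 CPM in replicate 2, and erythroid markers to 502 and 145 CPM. Replicate 2 also correlated more closely with the mean CB profile across genes (0.855) than the other CC libraries did (0.766 to 0.772). Its correlation with the single CB libraries (0.841 to 0.854) exceeded that with Smarca4+/- CC replicate 1 (0.769). Replicate 2 had the largest total of the CC libraries (837558 counts), and depth was not separated from these correlations. Mitochondrial genome genes rose in 6 of 10, such as mt-Nd5 (2.57, SE 0.29; camera adjusted p = 1.17e-16; adjusted p = 0.122 with an estimated correlation).

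**Figure D4:**
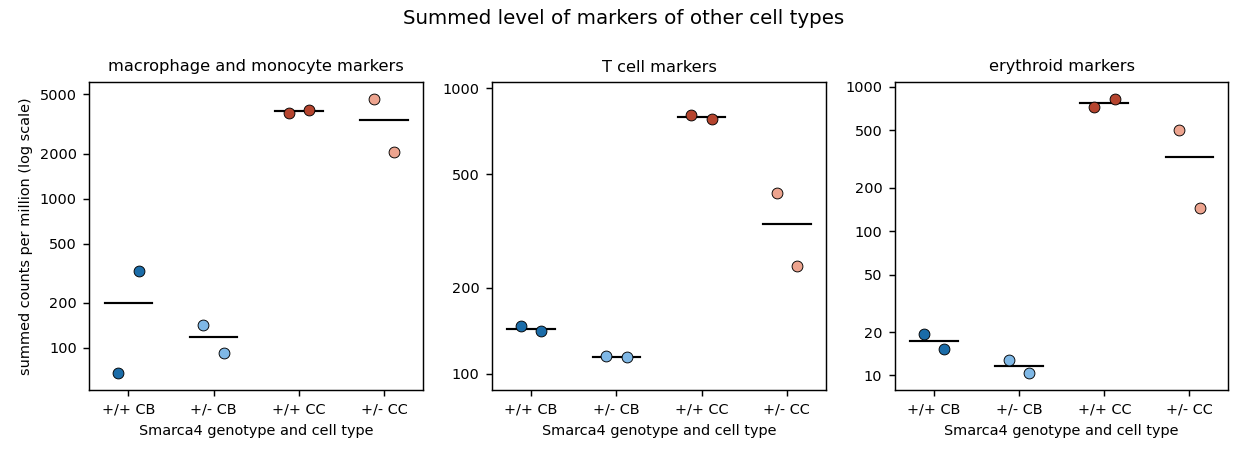
Summed level of macrophage, T cell and erythroid markers in CPM (log scale) in each library (points) with the group mean (line). All 4 CC libraries lie above all 4 CB libraries for each list, and the lowest CC value is that of Smarca4+/- CC replicate 2 (2063, 239 and 145).

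Over all genes in Smarca4+/- cells, 282 rose and 195 fell from CB to CC. Among the largest increases by rule were those in Marco, Vwf, Col4a1, Sox6, Enpp2, Hba-a2, Cd27, Ccr6, Als2cl, Hba-a1 and Cd3g, and among the largest decreases those in Ret, Hist3h2ba, Tifa, Mybpc2, Otub2, Hist1h2an, Cep76, Mmgt1, Slco4a1, Lmo4, Hspa2 and Ccdc124. Marco, a scavenger receptor of macrophages, was at least 139.7-fold higher, and Ret, Hist3h2ba and Tifa were at least 7.79-fold, 7.28-fold and 6.2-fold lower. The rank of these genes rests on a fitted change against a group at 0. Of 34 lists camera called 24, and fry called 21. Smarca4 fell in CC in this genotype too (-1.37, SE 0.18, adjusted p = 0.00318). The median of all genes was -0.08 with TMM, 0.03 with RLE and 0.04 with total counts, and the split of higher and lower genes became 305 and 122 with RLE and 326 and 99 with total counts. The count was 0 by edgeR without either Smarca4+/- CB library, 64 without CC replicate 1 and 932 without CC replicate 2, against 1487 with DESeq2, 1142 without the low count filter, 391 with limma-voom, 308 with only the groups compared, 270 with CB thinned and 2359 at an unadjusted p under 0.05.

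The CC against CB changes of both genotypes, which shared no library, overlapped. In both, 339 genes were called, all in the same direction (221 higher and 118 lower), where 17.8 would be called in both and in the same direction if the calls were independent. Across all genes the log2 fold changes correlated at 0.298 (Spearman) and 0.328 (Pearson), a description only, since genes are not independent replicates.

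Between genotypes in the CC libraries, 3 genes fell in Smarca4+/- and 0 rose, all at the immunoglobulin heavy chain locus on chromosome 12. Igha, the constant region of IgA (113254830 to 113260236), fell from 694 ± 15.5 to 27.1 ± 11.9 CPM (SD, n = 2; log2 fold change -4.66, SE 0.56, adjusted p = 0.0175). Ighg2b, the constant region of IgG2b (113302965 to 113307933), fell from 461 ± 78.4 to 109 ± 10.4 CPM (SD, n = 2; -2.08, SE 0.22, adjusted p = 0.00883). In CB, Igha stood at 80.7 and 23.0 CPM in Smarca4+/+ and at 12.9 and 11.6 CPM in Smarca4+/-. Ighg2b stood there at 142 and 149 CPM and at 168 and 142 CPM. For both genes the Smarca4+/- CC libraries thus lay near the CB libraries, and the Smarca4+/+ CC libraries stood apart. The variable segment Ighv1-42 (114937113 to 114937544) fell from 226 ± 41.3 to 7.56 ± 0.635 CPM (SD, n = 2; -4.90, SE 0.49, adjusted p = 0.00883). In the same libraries Ighg3 stood at 1.46 (SE 0.32, adjusted p = 0.114), higher in both Smarca4+/- CC libraries. The constant and J chain list had a median of -0.54 and a mean of 0.71, and camera gave a lower list (adjusted p = 0.000788; adjusted p = 0.358 with an estimated correlation; fry adjusted p = 0.0197). Adjusted over the list alone, 5 of its 13 members fell and 2 rose. The edgeR count of 3 was 0 with limma-voom, 323 without the low count filter, 846 with DESeq2 and 1980 at an unadjusted p under 0.05. The 3 calls also rested on Smarca4+/+ CC replicate 2 and on each Smarca4+/- CC library. Without Smarca4+/+ CC replicate 1 not all of them held, and with only the groups compared 2 of them held. The fit used 1 spread per gene for all groups. Replicates varied more in CC (coefficient of variation 0.434 and 0.393) than in CB (0.261 and 0.182), so its p ran small in CC. The simulated fit gave 26 false calls for this contrast. Neither the 3 calls nor the 1980 genes can therefore be read against the 650 expected by chance.

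**Figure D5:**
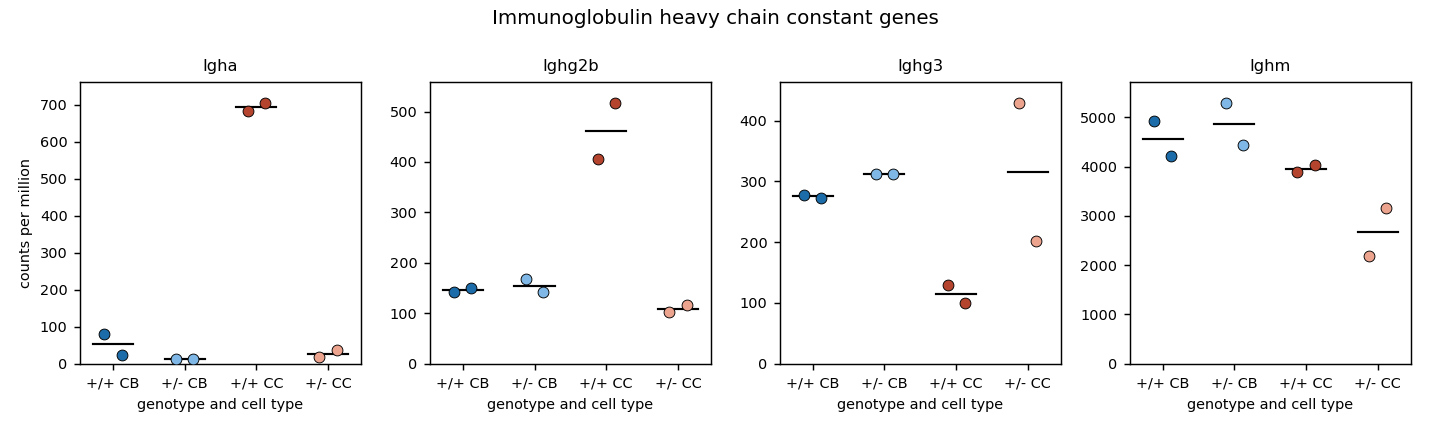
Level of 4 immunoglobulin heavy chain constant genes in CPM in each library (points) with the group mean (line). Igha reads 683 and 705 in the Smarca4+/+ CC libraries and 18.7 and 35.6 in the Smarca4+/- CC libraries, while Ighg3 reads 129 and 99.7 against 429 and 202.

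Mitotic genes as a list were higher in Smarca4+/- than in Smarca4+/+ CC. Of the 29 genes of G2/M and mitosis, 28 had a positive log2 fold change (median 1.01), 0 passed the edgeR test over all genes and 18 rose when adjusted over the list alone. Mki67 stood at 1078 ± 72.6 CPM in Smarca4+/+ and 2176 ± 563 in Smarca4+/- CC (SD, n = 2), a log2 fold change of 1.01 (SE 0.19, adjusted p = 0.1), and Aurka at 3.04 (SE 0.59, adjusted p = 0.103). The list's camera adjusted p was 1.12e-12, and adjusted p = 0.358 with an estimated correlation. Histones were positive in 51 of 58 (median 0.77, 14 rose when adjusted over the list alone, camera adjusted p = 4.07e-09; adjusted p = 0.358 with an estimated correlation). The genes of smallest p after the 3 called were Anln (4.64), Hist1h1e (1.47), Rab11fip4 (-3.10), Nus1 (3.77), Foxm1 (2.24), Ly6a (-2.08) and Tmpo (1.12), each with adjusted p = 0.0948. Foxm1 is a transcription factor of mitotic genes and Anln a protein of cytokinesis. Without Smarca4+/- CC replicate 2 the camera adjusted p was 0.000266 for G2/M and 0.00735 for histones.

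Other lists moved in CC with the genotype, each with adjusted p = 0.358 with an estimated correlation unless another is given. T cell markers were lower in Smarca4+/- CC (15 of 16 negative, camera adjusted p = 9.99e-05), summing to 808 and 781 CPM in Smarca4+/+ against 430 and 239 CPM, and erythroid markers were negative in 9 of 10 (0.00561; adjusted p = 0.406 with an estimated correlation). Ribosomal proteins were negative in 53 of 78 (median -0.30, camera adjusted p = 0.000204), and genes of migration in 14 of 18 (0.00964; fry adjusted p = 0.0189). Naive markers were negative in 9 of 11 (0.00913), memory genes in 14 of 19 (median -0.84, mean 0.28, adjusted p = 0.0124), MHC class II genes in 9 of 11 (0.0174; adjusted p = 0.491 with an estimated correlation) and interferon genes in 16 of 23 (median -0.70, mean 0.84, adjusted p = 0.0489; adjusted p = 0.501 with an estimated correlation). Stress and heat shock genes were negative in 11 of 14 (0.0318). Genes of cholesterol synthesis were positive in 14 of 19 (0.0308), G1/S genes in 19 of 28 (0.0489; adjusted p = 0.501 with an estimated correlation) and granulocyte markers in 5 of 5 (0.00218), the last summing to 252 and 78.2 CPM in Smarca4+/- and to 0 in both Smarca4+/+ CC libraries. None of these genes passed the edgeR test over all genes. With the replicate block the G1/S call ended (camera adjusted p = 0.0553). Without Smarca4+/- CC replicate 2 the calls ended for T cell (0.0657) and erythroid markers (0.24) and for naive (0.162), memory (0.233), cholesterol (0.199), interferon (0.549) and G1/S genes (0.375), and without replicate 1 for MHC class II genes (0.125), stress genes (0.105) and granulocyte markers (0.0624). Without Smarca4+/+ CC replicate 1 they ended for G1/S (0.293), interferon (0.267), cholesterol (0.151) and stress genes (0.0632), without replicate 2 for MHC class II genes (0.104), with RLE scaling for G1/S and interferon genes (0.0533 each) and with CB thinned for stress genes (0.0913). Myc (-0.41, SE 0.29, adjusted p = 0.491), Cxcr4 (0.70, SE 0.32, adjusted p = 0.335), Bcl6 (0.38, SE 0.22, adjusted p = 0.423) and Prdm1 (0.28, SE 0.72, adjusted p = 0.902) did not pass.

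Between genotypes in the CB libraries, no gene passed the edgeR test. The count of 0 stood beside 84 genes at an unadjusted p under 0.05, 3 by DESeq2, 5 by limma-voom, 13 without the low count filter and 5 lower with only the groups compared. The 84 lay below the 650 expected by chance. The 1 spread per gene fitted to all groups also took in the CC replicates, which varied more (coefficient of variation 0.434 and 0.393, against 0.261 and 0.182 in CB). Its p therefore ran large in CB, and the count of 0 does not show that the genotypes were alike. Among the smallest p were those of Igha (-2.08), mt-Nd2 (-0.66), Hist1h4d (0.65), mt-Nd5 (-0.97), C4b (at least 9.99-fold higher), mt-Co1 (-0.94), mt-Nd4 (-1.04), Ccr6 (-3.37) and Fn1 (6.88), each with adjusted p = 1. Cxcr4 (0.33, SE 0.24), Bcl6 (-0.11, SE 0.21) and Myc (-0.01, SE 0.26) also had adjusted p = 1.

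As lists, several groups differed in Smarca4+/- CB by camera at the preset correlation. Histones were positive in 56 of 58 (median 0.50, camera adjusted p = 1.84e-37; adjusted p = 0.158 with an estimated correlation). Ribosomal proteins were positive in 75 of 78 (median 0.27, camera adjusted p = 5.79e-24; adjusted p = 0.13 with an estimated correlation), and oxidative phosphorylation genes encoded in the nucleus in 68 of 73 (median 0.25, camera adjusted p = 9.17e-11; adjusted p = 0.0612 with an estimated correlation). Mitochondrial genome genes were negative in 9 of 10 (median -0.85, camera adjusted p = 4.8e-18; adjusted p = 0.197 with an estimated correlation), summing to 14275 and 13162 CPM in Smarca4+/+ and 6776 and 7636 CPM in Smarca4+/- CB, and 4 fell when adjusted over the list alone. Genes of G2/M were positive in 27 of 29 (median 0.20, camera adjusted p = 1.71e-05; adjusted p = 0.516 with an estimated correlation), a call that ended without Smarca4+/+ CB replicate 1 (adjusted p = 0.134) or Smarca4+/- CB replicate 1 (adjusted p = 0.232). fry called 0 of these lists. Macrophage markers, which summed to 329 CPM in Smarca4+/+ CB replicate 2 and 68.2 to 143 CPM in the other CB libraries, were lower as a list (adjusted p = 0.00883; adjusted p = 0.587 with an estimated correlation) and higher without that library (adjusted p = 4.1e-14). Also called by camera were the higher lists of G1/S genes (0.000146), immunoglobulin V segments (0.000155) and granulocyte markers (4.47e-09), with adjusted p = 0.287, 0.285 and 0.197 with an estimated correlation. The lower ones were T cell markers (0.00015), naive genes (0.000155), interferon genes (0.00231), light zone genes (0.00562), memory genes (0.0065), MHC class II genes (0.0147), erythroid markers (0.0201) and NF-kB genes (0.0424), with adjusted p = 0.302, 0.285, 0.291, 0.287, 0.287, 0.516, 0.516 and 0.516 with an estimated correlation. Without Smarca4+/+ CB replicate 1 the calls ended for T cell markers and naive genes (0.0993 each), light zone (0.2), MHC class II (0.511) and NF-kB genes (0.132), and without Smarca4+/- CB replicate 1 for V segments (0.724), G1/S (0.0518), light zone (0.0806), MHC class II (0.542) and NF-kB genes (0.127). Without Smarca4+/+ CB replicate 2 they ended for V segments (0.212) and NF-kB genes (0.0547). With CB thinned to the CC depth the calls ended for naive (0.998, with no direction shown), light zone (0.277) and NF-kB genes (0.118).

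The interaction asks whether the genotype difference differed between CC and CB. No gene passed in edgeR (smallest adjusted p = 0.0733, Ighv1-42 at -4.88, SE 0.61), against 1195 genes at an unadjusted p under 0.05, 339 by DESeq2 and 46 without the low count filter. The edgeR count was 1 with the replicate block and 13 with the replicate block within genotype. Among the next smallest p were those of Ighg2b (-2.17, SE 0.30, adjusted p = 0.0971), Anln (4.55), Nus1 (3.82) and Foxm1 (2.22), the last 3 with adjusted p = 0.419. As lists, G2/M genes were positive in 28 of 29 (median 0.77, camera adjusted p = 1.44e-07; adjusted p = 0.778 with an estimated correlation) and ribosomal proteins negative in 66 of 78 (median -0.54, camera adjusted p = 5.84e-12; adjusted p = 0.318 with an estimated correlation). Smarca4 stood at 0.21 (SE 0.25, adjusted p = 0.806). The genotype changes in CB and CC correlated across genes at 0.00800 (Spearman) and 0.0262 (Pearson).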

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

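Chosen after the results were seen were the tests of carry-over, of 1 library as the whole cause, of dilution, of depth, of other cells and of a few genes taking most of the counts, those of depth and of other cells in place of earlier ones (a ratio of summed levels with CB thinned, 1.44 or more, and the order of the macrophage genes) that could not have come out otherwise or could not separate the sources, while the list tests and the fits with a library left out were fixed before the data were examined, and the length and GC content tests were written after their pattern was seen but before their outcome was.

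In 4 gene lists the genotype difference differed between CC and CB, by a test of the interaction itself (camera). The adjusted p was 5.84e-12 for ribosomal proteins, 1.44e-07 for genes of G2/M and mitosis, 0.0122 for immunoglobulin constant and J chain genes and 0.0287 for oxidative phosphorylation. With an estimated correlation 0 of these calls held, and fry called 0. The immunoglobulin list had a median interaction of -0.66 and a mean of 0.84. The oxidative phosphorylation call ended without Smarca4+/+ CC replicate 2 (adjusted p = 0.155), Smarca4+/- CC replicate 1 (0.0735) or Smarca4+/- CB replicate 2 (0.0895).

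By camera at the preset correlation, genes of G2/M and histones were higher in the Smarca4+/- than in the Smarca4+/+ CC libraries; 0 members passed the edgeR test over all genes, adjusted p = 0.358 with an estimated correlation for both, and fry gave 0.139 and 0.148. At that preset, 1 Smarca4+/- CC library as the whole cause was argued against, since without either one both lists kept their call (largest adjusted p = 0.00735), and so was dilution of B cell RNA in the Smarca4+/+ CC libraries, since genes of B cell receptor signalling had a median log2 fold change of -0.11 (95% bootstrap interval -0.22 to 0.22) against 1.01 (0.77 to 1.40) for G2/M. Carry-over of CB cells into the Smarca4+/- CC libraries may contribute: Smarca4+/- CC replicate 2 had the highest G2/M sum of the CC libraries (5692 CPM, against 3723 in replicate 1), the highest correlation with the mean CB profile (0.855, against 0.766 to 0.772) and the lowest macrophage, T cell and erythroid sums. That library also had the largest total of the CC libraries (837558 counts), and depth was not separated from its correlation. Genes outside the cycle lists called lower in Smarca4+/+ CC closed a median of 42.2% (38.6% to 47.0%) of their gap to CB, against 33.1% (20.8% to 42.2%) for G2/M, a value that cannot be told apart from selection, since the share was -8.12% for genes called lower in Smarca4+/- CC and 7.95% for those called in both genotypes, selections added after the first value was seen, while fixed lists were too spread to decide (dark zone genes 15.2%, 0% to 50.9%; transcription factors 19.1%, -13.3% to 60.0%; histones, part of the pattern, 24.7%). An effect of genotype on the cycle of centrocytes stays open, untested.

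Macrophage, T cell and erythroid markers were higher in the CC than in the CB libraries. Lower depth of the CC libraries as the whole cause was argued against by the sums themselves, while thinning could not decide it. With CB thinned to that depth, the 3 lists stayed called by camera at the preset correlation in both genotypes (largest adjusted p = 1.18e-07). Thinning moved the median of all genes by at least 0.11 and ended other list calls. It keeps each gene's expected share of the counts, however. Before thinning, the lowest CC sum over the highest CB sum was 6.27 for macrophage, 1.63 for T cell and 7.42 for erythroid markers. After it the values were 6.97, 1.44 and 7.09. This test, like the one it replaced, could therefore hardly have come out otherwise. Lower depth likewise leaves a gene's expected share of the counts as it is. For each of the 3 lists, all 4 CC sums lay above all 4 CB sums, which argues against depth as the whole cause of the higher sums. Cells or RNA of other types in the CC libraries remain a candidate explanation. Of the 43 members of the 3 lists, 42 were higher in CC in both genotypes. Such a joint rise in markers of 3 other lineages argues against expression by centrocytes as the whole source, while the source of any single gene was not separated. CC libraries with more of these markers held less of the B cell receptor signalling genes (Spearman -0.8, Pearson -0.713, 4 libraries). The exact 1-sided p of the former was 0.167, where 0.0417 is the smallest that 4 libraries can give, so that test could not decide. The markers kept their order of level between CC libraries (Spearman of at least 0.933 over 17 macrophage genes, with Csf1r at 582.5 and 781.4 CPM in Smarca4+/+ CC), which either source would give. The PNA bead isolation and the later CB and CC separation would be the steps to remove such cells, and 1 of the T cell markers, Lck, made up most of the T cell sum in CB.

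By camera at the preset correlation, ribosomal protein and oxidative phosphorylation genes were higher in the Smarca4+/- CB libraries; 0 of 78 and 0 of 73 members passed the edgeR test, adjusted p = 0.13 and 0.0612 with an estimated correlation, and fry gave 0.351 for both, so the shift itself is not established. Gene length and GC content were argued against as the whole cause of the medians, since 95.9% of the ribosomal and 84.6% of the oxidative phosphorylation median were left after a trend on both was removed. Whether the share of the counts taken by a few genes caused the shift was left undecided. Removing the ribosomal RNA locus and mitochondrial genome genes moved nothing in this contrast (99.7% of the medians was left). An effect of genotype may stand behind the shift, as an untested possibility only, because library preparation and other batches are not given in the sources used here and could follow genotype.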

How the results depend on the processing

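The thinned CB libraries and the fit without ribosomal RNA locus and mitochondrial genes were chosen after the data were seen. Each lone library left in a group was assumed to vary like the other groups. Counts of changed genes for genotype in CB, genotype in CC, CC against CB in Smarca4+/+, the same in Smarca4+/- and the interaction were 0, 3, 973, 477 and 0. They became 3, 846, 2167, 1487 and 339 with DESeq2 and 13, 323, 1651, 1142 and 46 without the low count filter. With CB thinned, genotype in CC, both CC against CB counts and the interaction became 5, 579, 270 and 1. With only the groups compared, genotype in CB and both CC against CB counts became 5, 292 and 308. limma-voom gave 5 for genotype in CB and 0 for genotype in CC, which also had 0 without immunoglobulin genes, its 3 genes being of that kind. The interaction had 1 gene with the replicate block and 13 with the replicate block within genotype. Differences between replicates of equal number correlated at -0.0868 to 0.0745 across genes between groups, while replicate 2 had the larger total and ribosomal RNA locus share in all 4 groups. The replicate block gave 812 genes for CC against CB in Smarca4+/+ (771 shared). Leaving out 1 library gave 0 to 1, 0 to 3, 222 to 1131, 0 to 932 and 0 to 1 genes. Smarca4 in CC against CB of Smarca4+/- cells ranged from -1.58 to -1.23 and lost its call without either CB library of that genotype. Lists called by camera numbered 17, 15, 21, 24 and 4, and 0 in every contrast with an estimated correlation. With fry they were 0, 2, 14, 21 and 0. Leaving out 1 library gave 8 to 17 lists for genotype in CC and 5 to 10 for the interaction, and thinning gave 8 for the latter. The correlation between genotypes of the CC against CB changes was 0.298, 0.411 among genes of at least 5 CPM and 0.442 with CB thinned. Reversed were the naive follicular B cell markers for genotype in CB with CB thinned (adjusted p = 0.998) and the macrophage and monocyte markers there without Smarca4+/+ CB replicate 2 (adjusted p = 4.1e-14; 1.69e-50 to 0.587 over the libraries left out). The cause was not tested for these changes, apart from the immunoglobulin genes. Counted once per named gene and setting, results that kept direction and side of the threshold numbered 1735 in CC against CB of Smarca4+/+ cells and 1406 of Smarca4+/- cells, while 298 and 369 lost their call and 71 and 96 gained one.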

Other observations

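Several lists not described above had few called members. In Smarca4+/+ CC against CB, B cell receptor signalling genes fell in 2 of 22 (such as Dok3 at -1.19, SE 0.23; camera adjusted p = 0.216), and MHC class II genes split, with the protease gene Ctss higher (1.16, SE 0.23) and H2-DMb1 lower (-1.26, SE 0.33; camera adjusted p = 0.106). Interferon genes rose in 2 of 23, Bst2 (3.19, SE 0.77) and Stat2 (1.05, SE 0.25; camera adjusted p = 5.68e-05; adjusted p = 0.15 with an estimated correlation). Of the BCL2 family, Bcl2 rose and the death gene Bcl2l11 fell (-1.23, SE 0.29; camera adjusted p = 0.82). Plasma cell genes rose in 3 of 16 and fell in 1 (adjusted p = 0.395), and glycolysis genes split into Slc2a3 (2.63, SE 0.55) and Tpi1 (-0.93, SE 0.22; adjusted p = 0.697). Cholesterol synthesis had 0 called of 19 by edgeR (camera adjusted p = 0.923) and 0 of 14 stress genes passed (camera adjusted p = 0.185). Ribosomal proteins were higher (1 of 78 rose, camera adjusted p = 0.00338; 0.0757 without Smarca4+/+ CC replicate 2 and 0.0531 without Smarca4+/+ CB replicate 2; adjusted p = 0.336 with an estimated correlation), oxidative phosphorylation had an adjusted p of 0.311, and immunoglobulin V segments 0.311 with 3 higher and 3 lower of 170. Stromal and endothelial markers rose in 1 of 6 (Col1a2, at least 144.8-fold; camera adjusted p = 0.00211; 0.0658 without Smarca4+/+ CC replicate 1; adjusted p = 0.332 with an estimated correlation). The constant region list, NK markers, granulocyte markers and sex-linked genes had adjusted p = 0.216, 0.216, 0.851 and 0.503, and the single measured platelet marker, Itgb3, stood at -1.46 (SE 0.43, adjusted p = 0.0661).

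In Smarca4+/- CC against CB, ribosomal proteins were lower (59 of 78 negative, Rps15a at -1.08, SE 0.23; camera adjusted p = 0.000251; adjusted p = 0.229 with an estimated correlation) and oxidative phosphorylation genes too (63 of 73 negative, camera adjusted p = 4.34e-05; adjusted p = 0.0794 with an estimated correlation). Cholesterol synthesis genes were positive in 14 of 19 (camera adjusted p = 0.0126; adjusted p = 0.122 with an estimated correlation), and granulocyte markers in 5 of 5 (0.00168; adjusted p = 0.229 with an estimated correlation), with none past the edgeR test. Those calls ended without Smarca4+/- CC replicate 2 (0.154) and replicate 1 (0.0679). Pdia4 rose (1.39, SE 0.32) as the 1 called gene of 16 in the unfolded protein response list (camera adjusted p = 0.0708). B cell receptor signalling (adjusted p = 0.149) and MHC class II genes (0.605) had 0 called members by edgeR.

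The gene Lars2 stood at 7832 CPM in Smarca4+/+ CC replicate 1 and at 90.1 to 392 CPM in the other libraries. The Y-linked gene Kdm5d had 10 to 845 counts in 7 libraries and 0 in Smarca4+/- CC replicate 1, while Xist was read in all 8 (434 counts or more). Uty had 0 counts in both Smarca4+/+ CC libraries, and Eif2s3y had 0 in replicate 2 of them. The sex of the mice and any pooling are not given in the sources used here, so reads of Xist and Kdm5d in 1 library leave open whether a library is 1 mouse, and with it what n = 2 stands for. Ighg2c had 0 counts in both Smarca4+/+ CC libraries and 13 and 26 in the Smarca4+/- CC libraries. These features were picked after their values were seen.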
